A study of Mus musculus with 28 samples.

How the data were processed

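Gene expression was measured in 28 libraries of cells sorted from the lungs of C57BL/6 mice aged 8 weeks. Per the labels, the sorted cells were type 1 and type 2 alveolar epithelial cells (AEC1, AEC2), group 2 innate lymphoid cells (ILC2) and basophils. The mice were untreated, or received papain, or received papain with FK506. Papain is a plant cysteine protease used to provoke allergic lung inflammation, and FK506 (tacrolimus) is an inhibitor of the phosphatase calcineurin. Per the labels, papain was given through the nose at 50 µg per day. FK506 was injected into the peritoneum at 0.2 mg per animal per day in courses of 3 days that lay 2 days apart, the later course together with papain. Libraries were prepared from 10 ng of total RNA with a Lexogen QuantSeq kit, which reads the 3' ends of transcripts, and were sequenced on a HiSeq instrument, per the labels' protocols.

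The submitters' processing notes name STAR 2.7.0c, featureCounts 1.6.0 and the mouse genome builds mm10 and GRCm38.p6, with no role or setting for any of them. The authors deposited CPM (read counts scaled to a common library total) for the AEC1, AEC2 and basophil libraries, with 1 exception. The values of the AEC2 untreated replicate 1 and of all 9 ILC2 libraries are whole numbers on the CPM scale, and they were treated as a score, that is, deposited CPM values rounded by the authors. No raw counts were used here. What the values are divided by is not given in the sources used here. Strand setting and the handling of reads that match several genes are not given either, so genes with near-identical copies, such as those of the class II and class I histocompatibility, secretoglobin and chemokine families, are uncertain. Gapdh, which every cell uses, was listed at 0 in most libraries. A value of 0 therefore means only that a gene was listed at 0, and no fold is given against a group listed at 0. The ILC2 and basophil tables lacked the mitochondrial and 18S ribosomal RNA genes that the AEC tables hold, and 27 genes had no value in the ILC2 replicate 3 tables.

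Depth was estimated from the largest step of which nearly all values below 25 CPM were whole multiples. That step was taken as the value of 1 read. It gave 847782 to 975465 reads for AEC1 and 1206886 to 1336079 reads for AEC2. In all 6 AEC1 libraries and in 5 AEC2 libraries, 100% of these low values fell within 0.1 read of a whole number. That share follows largely from the choice of the step and is no separate check of the depth. For the basophil libraries 61.4 to 98.0% of the low values came out whole. Their estimated library totals of 2078431 to 3123909 reads are approximate, and exceed the reads behind the listed values. For the rounded values (ILC2 and AEC2 untreated replicate 1) the depth is unknown. One read was thus worth about 1 CPM in AEC libraries, and single-read sampling sets a floor on the precision of low genes.

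Groups were taken from the labels. Genes entered a comparison when they reached 10 CPM in at least as many libraries as the smallest replicated group of that cell type. Values were divided by TMM (trimmed mean of M values) factors from edgeR 4.0.16, 2 CPM were added, and log2 values were fitted with limma 3.58.1 (empirical Bayes with a trend of variance on expression, not robust) in R 4.3.3. Fold changes are on this log2(CPM + 2) scale, which understates the change of low genes. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All libraries of a cell type shared 1 estimate of the spread. For ILC2 a batch term was fitted, because replicates 1 and 2 of each group carry 1 code in their file names and replicate 3 carries the code of the basophil libraries. The difference between cell types in the response to FK506 or papain was tested as an interaction term. The design written before the data were examined had assumed raw counts and edgeR's quasi-likelihood test. Because the deposited unit is CPM, limma took its place, and edgeR, DESeq2 1.42.0 and limma's voom were run as alternatives on the reads recovered for AEC libraries.

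A set of 34 gene lists (pathways and markers of lung cell types) was fixed before any value was seen, as were the comparisons, the batch term and the naming of genes. Each list with at least 5 tested members was tested with camera at a preset correlation between genes of 0.01, which asks whether its members rank above or below the other genes. Camera was repeated with an estimated correlation (statmod 1.5.0 was installed), under which every list call was lost, and fry was run, which asks whether the members move on balance one way. For list members, calls were also counted with p adjusted over the list alone. That adjustment does not allow for the number of lists or comparisons, so members that pass only in this way are weaker calls. Genes were named by rule: in each comparison up to 8 that rose most and 8 that fell most among passing genes whose groups did not overlap and whose mean was at least 5 CPM, up to 4 passing members of each list, a fixed set of cytokine, receptor and marker genes whatever their p, and, where fewer than 5 genes passed, the 5 with the smallest p, given as values. List members named beyond this rule (those passing only over the list alone, and examples of marker levels) were chosen after their values were seen. Gene positions are from a GRCm38.p6 annotation.

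The procedure was tested on simulated data made from each cell type's own means and spread with 200 changed genes, drawn from those above the median expression. The shares below are therefore not those of all tested genes. The simulated noise was normal and alike in all libraries of a cell type, without a batch effect. For log2 changes of 4, it recovered 15 to 20% of changed genes in the ILC2 comparisons, 13% in basophils with papain against untreated, 37% in basophils with papain and FK506 against papain, 0 to 1% in AEC2 and 1 to 6% in AEC1. For log2 changes of 2 the shares were 4 to 5% in ILC2, 0 and 9% in basophils and 0% in both epithelial types. At most 1 false call was made in a comparison under this simulated noise, which lacks features of the real libraries. Low counts of called genes are therefore weak evidence about the absence of change. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these samples, which can be technical.

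The alternatives were other scalings, expression minimums, pseudocounts, subsets of groups, the batch term, the replicate number as a block, other tools and leaving out each library. A robust limma fit and a fit with array weights were run by mistake before the setting reported here. Their output was seen first, and both are kept as alternatives chosen after the data were seen.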

Results

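The series compared 4 cell populations of the mouse lung in 3 conditions. There were 9 ILC2 libraries (3 untreated, 3 papain, 3 papain with FK506), 7 basophil libraries (1 untreated, whose title names controls 1 and 2, 3 papain and 3 papain with FK506), 6 AEC2 libraries and 6 AEC1 libraries (2 per condition). The deposited CPM values summed to between 986819 and 992527 in AEC1 and between 989855 and 992311 in AEC2. In basophils they summed to between 612434 and 672357, and in ILC2 to between 519768 and 636598. The library totals on the CPM scale, where they could be estimated, numbered 847782 to 975465 reads in AEC1, 1206886 to 1336079 in AEC2 and about 2078431 to 3123909 in basophils. The listed basophil values sum to less than such a total, so fewer reads lie behind them. Genes above 0 numbered 6334 to 7334 in AEC1, 4441 to 6507 in AEC2, 2002 to 7894 in basophils and 3134 to 7240 in ILC2. The 10 highest genes took 22.9 to 41.4% of the values in AEC1.

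The libraries of each population were described by marker genes fixed in advance. In AEC2, Sftpc (surfactant protein C, secreted by type 2 cells) stood at 61276 and 42260 CPM in the untreated libraries, and the AEC2 markers together summed to between 135344 and 166115 CPM in the 6 libraries. In AEC1, fibroblast and smooth muscle markers summed to 9954 to 27218 CPM and mesothelial markers to 1804 to 6354 CPM, above the AEC1 markers, which summed to 1089 to 1905 CPM. The AEC1 markers summed to more in every AEC2 library (2009 to 4659 CPM). Of the 20 members, 5 to 12 were at 0 in AEC1 libraries and 8 to 11 in AEC2 libraries. Results given for AEC1 are therefore those of libraries with this label, and how many type 1 cells they held is not known. Ager, a receptor abundant on type 1 cells, stood at 50.5 and 75.9 CPM in the untreated AEC1 libraries. In ILC2, the transcription factor gene Gata3 stood at 391, 807 and 440 CPM in the untreated libraries and Il1rl1, which encodes the IL-33 receptor, at 264, 383 and 44 CPM. Epithelial transcripts were largely in ILC2 replicate 3: AEC2 markers summed to 5341, 7163 and 5378 CPM in the untreated, papain and papain with FK506 replicate 3, against 10 to 669 CPM in the other 6 ILC2 libraries. In basophils, Mcpt8 (mast cell protease 8, a granule protease of basophils) and Fcer1a (the alpha chain of the IgE receptor) were listed at 0 in all 7 libraries. Macrophage, monocyte and dendritic cell markers summed to 4508 to 14426 CPM there, with 1 to 6 of 20 members at 0, and the basophil markers, several of them shared with other myeloid cells, to 807 to 2493 CPM. In AEC2 the macrophage list summed to 5912 to 14315 CPM, with 15 to 17 of 20 members at 0. That sum was mostly of the lysozyme genes Lyz2 (6779 and 4796.9 CPM in untreated) and Lyz1 (3173 and 1596.7 CPM), of which Lyz2 is also made by type 2 cells, and Csf1r, the macrophage growth factor receptor gene, was listed at 0 in all 6 AEC2 libraries.

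**Figure D1:**
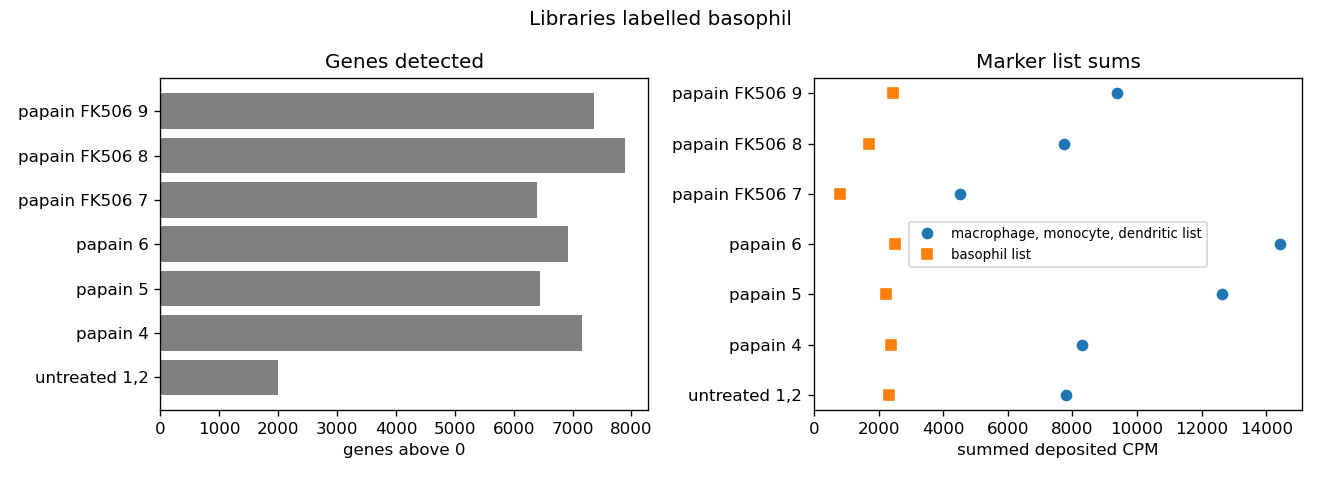
Genes above 0 (bars) and summed CPM of the macrophage, monocyte and dendritic cell list and of the basophil list (points) in each of the 7 basophil libraries. The untreated library has 2002 genes above 0, the lowest of the 7, and the macrophage list exceeds the basophil list in every library.

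The response of ILC2 to papain was asked first. Il13, the cytokine of mucus production and airway hyperreactivity (GRCm38.p6 chromosome 11, 53631323 to 53634702), stood at 386, 182 and 66 CPM with papain and at 30, 56 and 0 CPM in untreated cells, a log2 difference of 3.14 (SE 1.31, limma adjusted p = 0.985). The epidermal growth factor family member Areg stood at 250, 184 and 649 CPM against 71, 176 and 64 CPM, and Il5, the eosinophil growth factor, at 65, 45 and 0 CPM against 33, 14 and 0 CPM. The cytokine genes Il4 and Il9 were listed at 0 in all 9 libraries. Gata3, the master transcription factor of ILC2, stood at 255, 166 and 56 CPM with papain (log2 difference -2.21, SE 0.93, adjusted p = 0.985). None of these genes passed the test. Those with the smallest p did not pass either. They were the AP-1 subunit genes Junb (-0.80, SE 0.16, adjusted p = 0.0769), Fosl2 (-2.02, adjusted p = 0.0982) and Fosb (-1.89, adjusted p = 0.222). They also held the nuclear noncoding RNA Malat1 (-0.94, adjusted p = 0.0982) and the neutrophil chemoattractant Cxcl2 (-1.07, adjusted p = 0.147). Among 6271 genes limma called 0, with 234 at an unadjusted p under 0.05 where 314 would be given by chance. The groups did not overlap for 460 genes, which chance gives for 10% of genes with 3 libraries against 3.

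As groups, the 17 tested cell cycle genes ranked above the other genes with papain in ILC2 (camera adjusted p = 0.0145; adjusted p = 0.882 with an estimated correlation). Of them 0 passed adjusted over the list alone. Examples are Ube2c, the ubiquitin-conjugating enzyme of mitotic exit, at 73, 13 and 98 CPM against 0 in all untreated libraries, and the mitotic kinase gene Plk1 at 37, 47 and 122 CPM against 0. The 22 immediate early and cell isolation stress genes, which are switched on within minutes by stimulation or tissue digestion, ranked below the others (camera adjusted p = 7.64e-07; adjusted p = 0.882 with an estimated correlation). Junb and Fosb fell when adjusted over the list alone. The AEC2, fibroblast and airway marker sums differed between replicate 3 of untreated ILC2 and the other untreated libraries, with airway markers at 38658 CPM against 13 and 33 CPM.

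**Figure D2:**
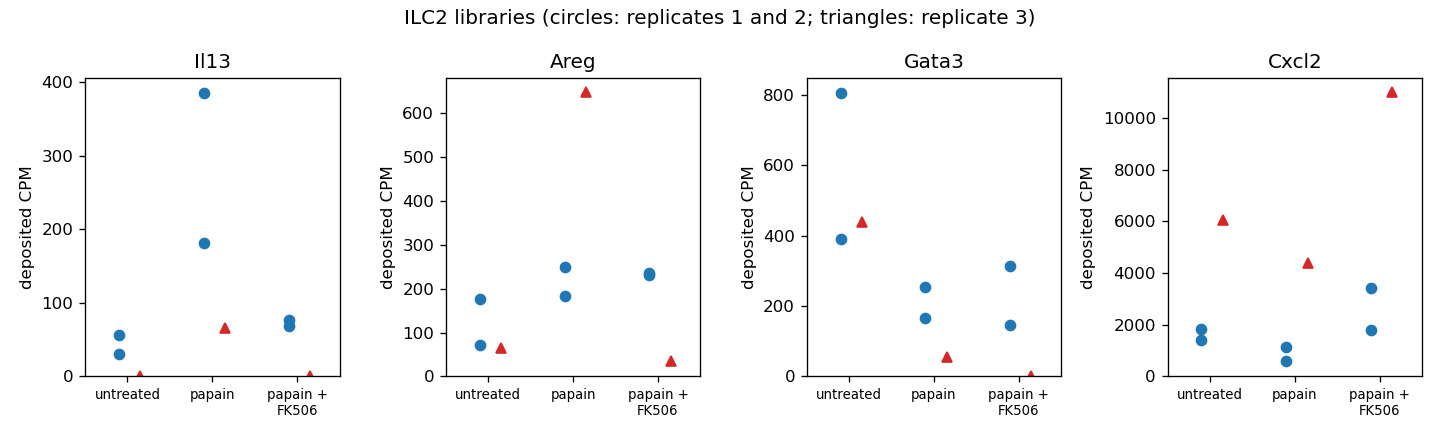
Deposited CPM of Il13, Areg, Gata3 and Cxcl2 in the 9 ILC2 libraries by condition, with circles for replicates 1 and 2 and triangles for replicate 3, which carries another file code. Il13 lies between 66 and 386 CPM with papain and between 0 and 77 CPM with papain and FK506.

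The effect of FK506 on papain-treated ILC2 was the next comparison. Cxcl2 (chromosome 5, 90903899 to 90905938) rose with FK506, from 1141, 596 and 4398 CPM to 3411, 1801 and 11009 CPM, a log2 change of 1.58 (SE 0.25, limma adjusted p = 0.000635). Cxcl2 was the only gene of 6271 called, and its groups overlapped, since papain replicate 3 lay above papain with FK506 replicates 1 and 2. Its value was higher with FK506 within each replicate number of the titles, but these numbers do not pair the samples. Papain with FK506 replicate 3 also held macrophage markers at 9928 CPM, against 34 and 263 CPM in replicates 1 and 2. Whether the Cxcl2 of that library came from other cells was not tested. Il13 stood at 77, 68 and 0 CPM with FK506 against 386, 182 and 66 CPM with papain alone (log2 difference -2.87, SE 1.31, adjusted p = 0.910), and Areg at 231, 235 and 36 CPM. Csf2, which encodes the granulocyte and macrophage growth factor GM-CSF, stood at 0, 22 and 0 CPM against 34, 54 and 1 CPM. Rcan1, a calcineurin feedback gene, stood at 0, 0 and 72 CPM against 0, 29 and 188 CPM. The proliferation gene Mki67 was listed at 0 in all 3 libraries against 41, 36 and 0 CPM, and Il6 at 0, 0 and 53 CPM against 0, 6 and 0 CPM. None of these passed, nor did Psap, Il7r, Zcchc10 and Pim3, which had the smallest p after Cxcl2 (log2 differences 1.70, -3.27, -5.78 and 3.15). The Cxcl2 call was lost without ILC2 papain replicate 3 (adjusted p = 0.152), without papain with FK506 replicate 3 (adjusted p = 0.831) and with replicates 1 and 2 only (adjusted p = 0.758). It was also lost without the batch term (adjusted p = 0.0709), while its log2 change stayed between 1.23 and 1.87 and its adjusted p between 3.08e-09 and 0.831 over all alternatives.

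The 19 ILC2 identity and receptor genes ranked below the other genes with FK506 (camera adjusted p = 1.01e-05; adjusted p = 0.307 with an estimated correlation). Adjusted over the list alone, 2 fell: Il7r, the IL-7 receptor chain needed by innate lymphoid cells (log2 change -3.27, SE 0.81), and the nuclear receptor gene Rora, needed for ILC2 development (-2.06, SE 0.61). The same list summed to 1160 CPM in papain with FK506 replicate 3 and to between 2398 and 6166 CPM in the other 8 libraries. In that library the class II histocompatibility (MHC) genes summed to 20061 CPM and macrophage markers to 9928 CPM. Immediate early genes ranked above the others (camera adjusted p = 0.00867; adjusted p = 0.960 with an estimated correlation), with 0 members passing adjusted over the list alone. At an unadjusted p under 0.05 there were 262 genes against 314 by chance, and 429 genes had groups that did not overlap.

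In ILC2 with papain and FK506 against untreated ILC2, limma called 0 genes, with 250 at an unadjusted p under 0.05 and 523 whose groups did not overlap. Gata3 stood at 315, 145 and 0 CPM against 391, 807 and 440 CPM (log2 difference -3.74, SE 0.93, adjusted p = 0.431). Il13 differed by 0.26 on the log2 scale (SE 1.31). The genes with the smallest p also held Malat1 (-0.94, adjusted p = 0.214), Rora (-2.47, SE 0.61), the lysosomal protein gene Psap (1.49) and Junb (-0.59). The ILC2 identity genes ranked below the others (camera adjusted p = 0.00255; adjusted p = 0.815 with an estimated correlation), and Rora, Gata3 and Il7r fell when adjusted over the list alone. Papain with FK506 replicate 3, where Gata3 was listed at 0, had the lowest sum of this list (1160 CPM) and macrophage markers at 9928 CPM. A lower share of ILC2 in that library cannot be told apart from a change within ILC2. Of genes raised by papain and lowered by FK506 there were 0, because neither direction had a call. The log2 changes of both steps, which share the papain libraries, correlated across genes at r = -0.49, and 100 simulations without any effect gave -0.50 on average (-0.53 to -0.48). Genes are not independent replicates. The covariance was -1.04 against -0.95 in the simulations (-1.04 to -0.89).

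In basophils, papain was compared with a single untreated library, so the untreated state had no replicate and was assumed to vary like the treated groups. Every call in this comparison is a difference from that 1 library, and higher and lower are meant against it. Limma called 1351 of 5853 genes, 1234 higher and 117 lower in the papain libraries, and 2108 at an unadjusted p under 0.05, while the median of all genes was shifted by 3.05 on the log2 scale. Of 12 IL-4 and IL-13 response genes 4 were called higher and 1 lower, over all genes and adjusted over the list alone. The arginase gene Arg1 (chromosome 10, 24915207 to 24927470) was listed at 0 in the untreated library and stood at 364, 1511 and 2120 CPM with papain. Retnla, which encodes a secreted protein induced by IL-4 and IL-13, stood at 0.5 against 368, 1700 and 2299 CPM (adjusted p = 7.53e-05). Other genes with the largest differences upward were Lgals3 (galectin-3; 0 against 735, 1749 and 1910 CPM) and the calcium-binding protein gene S100a4 (0 against 570, 1163 and 1840 CPM). They also held the complement genes C1qb (0.5 against 721, 1357 and 1230 CPM) and C1qc, the ribosomal protein gene Rpl37 and the secretory pathway gene Tmed9. The macrophage, monocyte and dendritic cell list, which holds both complement genes, summed to 7811 CPM in untreated and 8302, 12629 and 14426 CPM with papain. Endothelial markers summed to 2884 CPM against 3207, 282.8 and 154.5 CPM, and neutrophil markers to 2662.5 CPM against 4192, 413 and 689 CPM, so papain replicate 4 stood apart. Those with the largest differences downward were Atl3, which shapes the endoplasmic reticulum (762.1 CPM against 0 in all 3), and Dkk3 (1006.5 CPM against 0, 0 and 3.4 CPM; -8.17, SE 2.35, adjusted p = 0.0201). They were followed by Ppif, Wrn, Acsl1, Tmem167b, Rc3h2 and Hacd3. The IL-4 receptor gene Il4ra was the member of the response list called lower, at 293.5, 464.7 and 173.2 CPM against 2021.2 CPM (-2.42, SE 0.62, adjusted p = 0.0102).

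The calls on lists stood within this shift of all basophil genes. Camera, which compares a list with the other genes, called 0 lists, and fry, which does not, called 13. Of 21 immediate early genes 9 were higher (10 higher and 1 lower adjusted over the list alone), among them Fos at 676.1, 1453.6 and 956.0 CPM against 4.3 CPM. Of 14 unfolded protein response genes 5 were higher, including the stress transcription factor genes Atf4 and Xbp1. Of 12 glycolysis genes 4 were higher (6 adjusted over the list alone), including Hk2 (0 against 128.7, 123.1 and 214.4 CPM) and Pkm (2.15, SE 0.61). Of 11 basophil markers 2 were higher, Ccr2 and Cebpa, both shared with monocytes. Of 8 fibroblast and smooth muscle markers 2 were higher and 3 lower, among the latter Gsn (-3.15, SE 0.69) and Inmt (-5.28, SE 1.41). Of the mediators, Alox5ap, a leukotriene synthesis gene, was higher (3.71, SE 0.79). Ccl4 passed too (0 against 69.5, 155.1 and 112.5 CPM, limma adjusted p = 0.0472), but its call was lost in 6 of 15 alternatives (highest adjusted p 0.251). Among these was leaving out papain replicate 4, 5 or 6 (adjusted p = 0.0805, 0.129 and 0.119). Ccl3 (0.39, adjusted p = 0.724), Tnf (0.08, adjusted p = 0.937), Il6, Csf1 and Rcan1 did not pass. Members of the calcineurin and NFAT list that did pass were Nr4a2, Nr4a3 and Ppp3ca, called higher, and Nr4a1, called lower. The call of Nr4a1 was lost in 4 of 15 alternatives. Il4 and Il13 were listed at 0 in all 7 libraries. With each papain library left out, 1107 to 1250 genes were called. The number called lower moved more than the total: it was 192 with size factors, 185 with library totals, 206 with the sum over listed genes and 68 without papain replicate 5, in place of 117. Of the genes named for papain, Acsl1 was lost without replicate 4 (adjusted p = 0.0509) or 6 (0.0581), Tmem167b without 4 (0.0733) or 5 (0.0822), and Pkm without 6 (0.0607). With no filter on expression the calls of all 8 genes with the largest differences downward were lost, among them Atl3 (adjusted p = 0.0559), Dkk3 (0.0720), Acsl1 (0.102) and Tmem167b (0.134), and so was that of Alox5ap (0.0516). The call of C1qc was lost in 3 of 15 alternatives (highest adjusted p 0.193) and that of Inmt in 4 (0.132).

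FK506 in papain-treated basophil libraries gave 0 limma calls among 5853 genes, with 354 at an unadjusted p under 0.05 against 293 by chance and 667 whose groups did not overlap. The 5 genes with the smallest p did not pass. Sftpc stood at 3463, 2401 and 667 CPM against 313.7, 202.3 and 245.1 CPM (log2 difference 2.77, SE 0.51, adjusted p = 0.222). The smooth muscle actin gene Acta2 stood at 559, 415 and 435 CPM against 66.6, 39.4 and 52.5 CPM (3.08, SE 0.61, adjusted p = 0.222) and the elastin gene Eln at 706, 1018 and 481 CPM against 146, 77 and 25 CPM (3.32, SE 0.67, adjusted p = 0.222). Rnase2a, an eosinophil-type ribonuclease gene, was listed at 0 in all 3 libraries with FK506 against 134.8, 211.3 and 544.8 CPM, and Nrgn differed by -3.87 (adjusted p = 0.311). Ccl3 differed by -0.64, Ccl4 by -1.38 and Tnf by 0.97 on the log2 scale, with none passing.

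By list, the 8 MHC class II genes, which present antigen to T cells, ranked below the other genes with FK506 in basophil libraries (camera adjusted p = 1.82e-08; adjusted p = 0.303 with an estimated correlation). Adjusted over the list alone 6 of them fell, among them H2-Ab1 (-2.63, SE 0.73), H2-Aa (-2.12, SE 0.68) and the invariant chain gene Cd74 (-2.06, SE 0.61). Macrophage markers (camera adjusted p = 0.0118; 0.551 with an estimated correlation) and p53 and apoptosis genes (0.0149; 0.303 with an estimated correlation) ranked lower too. Ranking higher were fibroblast and smooth muscle markers (5.3e-10; 0.292 with an estimated correlation), AEC2 markers (3.16e-08; 0.303), AEC1 markers (0.000287; 0.449), airway (0.00315; 0.441) and endothelial markers (0.00315; 0.581), and complement and acute phase genes (0.0118; 0.551). So did ILC2 identity genes (0.0261; 0.303) and cholesterol and fatty acid synthesis genes (0.0369; 0.303). In each pair the latter value is the adjusted p with an estimated correlation. The complement list shares the surfactant genes Sftpa1 and Sftpd with the AEC2 markers, so these ranks are not separate results. Adjusted over the list alone, 6 of 8 fibroblast, 6 of 13 AEC2, 2 of 5 airway, 3 of 12 complement and 1 of 13 AEC1 markers rose. These sums differed between single libraries. AEC2 markers stood at 12644, 10685 and 3301 CPM in replicates 7, 8 and 9 with FK506, and MHC class II genes at 1643, 12538 and 19499 CPM. Without replicates 7 and 8 limma called 0 genes, as it did with them, so that count does not show what they contribute.

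In AEC2 the question was whether the epithelium itself responded to papain. Retnla (chromosome 16, 48842609 to 48844461) stood at 7876.2 and 222.6 CPM with papain, 3124.1 and 1896.6 CPM with papain and FK506, and 42 and 210.1 CPM in untreated cells. Its log2 difference from untreated was 3.63 (SE 1.26, adjusted p = 1) for papain and 4.52 (SE 1.26, adjusted p = 0.909) for papain with FK506. Il33, the epithelial alarmin that activates ILC2 (chromosome 19, 29925113 to 29960718), stood at 42 and 335.5 CPM in untreated cells, 479.6 and 350 CPM with papain, and 690.8 and 609.8 CPM with FK506 added (2.28 against untreated, SE 0.83, adjusted p = 0.909). Lcn2, an antimicrobial iron-binding protein gene, stood at 329 and 484.8 CPM, 1934.8 and 502 CPM, and 1507.4 and 2214.8 CPM in the same order. Tslp, Il25, Csf1 and Csf2 were listed at 0 in all 6 libraries. Sftpc differed by -0.34 (SE 0.26) with papain and by -0.62 (SE 0.26) with papain and FK506. Limma called 0 of 6719 genes in each comparison. At an unadjusted p under 0.05 there were 15 (papain against untreated), 284 (FK506 added against papain) and 307 (papain with FK506 against untreated), against 336 by chance. The count tests on recovered reads left out the rounded library, untreated replicate 1. For FK506 added against papain, edgeR then called 0, DESeq2 63 and voom 5. Comparisons with untreated kept only untreated replicate 2, which was nearly alike with papain replicate 2 (described below). Their counts from these tools are therefore not given.

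The untreated replicate 2 and papain replicate 2 of AEC2 were nearly alike. Their log2 values correlated across genes at r = 0.985, and the chi-square of their recovered reads per degree of freedom was 2.42 against 46.0 to 74.7 for other AEC2 pairs. With replicate 1 of their own group they correlated at 0.395 (untreated) and 0.372 (papain). A pair alike across 2 groups lowers the difference of the group means relative to the spread within the groups. The 15 genes at an unadjusted p under 0.05 in limma therefore say little about the papain response. The simulated AEC2 data were made with the same spread. Each AEC2 comparison held at least 1 of the 2 nearly alike libraries. Without both, 1 untreated and 1 papain library were left, and the limma count of 0 there says nothing about the effect of this pair.

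**Figure D3:**
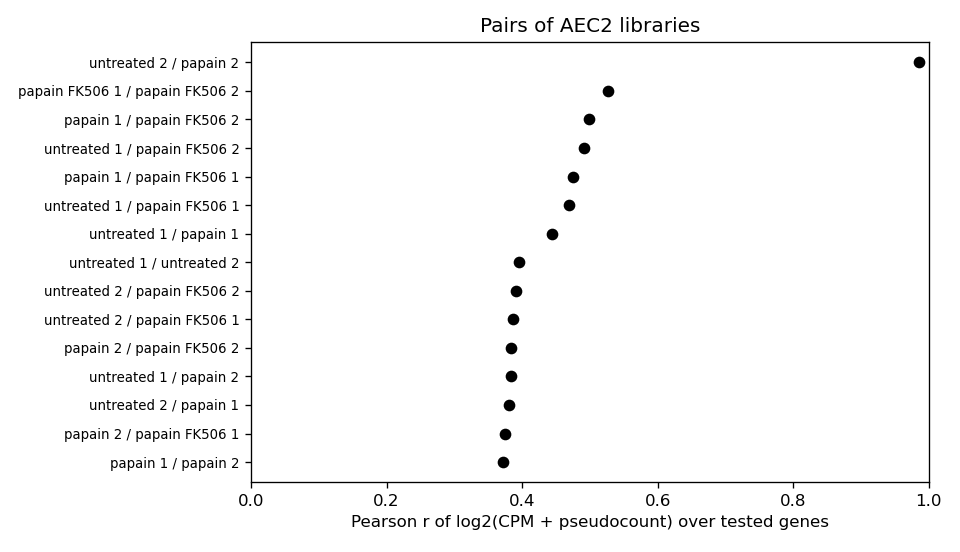
Pearson r across genes of log2(CPM + 2) for each pair of the 6 AEC2 libraries. The pair of untreated replicate 2 and papain replicate 2 stands at 0.985, above every other pair.

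By list in AEC2, the 19 cell cycle genes ranked above the other genes with papain against untreated (camera adjusted p = 0.0165; adjusted p = 0.796 with an estimated correlation). They also did so with FK506 added against papain (0.0023; adjusted p = 0.994 with an estimated correlation) and with papain and FK506 against untreated (2.24e-08; adjusted p = 0.718 with an estimated correlation). Of the papain libraries only replicate 1 lay above untreated in the list's sum, which was 1479 and 80.5 CPM with papain, 164 and 156 CPM in untreated, and 1772 and 1595 CPM with papain and FK506. Birc5, a survival and mitosis gene, stood at 229.8 and 129.3 CPM with papain and FK506 against 0 in both untreated libraries, and Cdk1, the mitotic kinase, at 241.8 and 109.4 CPM against 0. Complement and acute phase genes ranked higher with papain (0.0109; adjusted p = 0.796 with an estimated correlation) and with papain and FK506 against untreated (0.00107; adjusted p = 0.718 with an estimated correlation). They summed to 70573 and 49402 CPM in papain replicates 1 and 2 and to 35729 and 46979 CPM in untreated replicates 1 and 2, so that papain replicate 2 lay near untreated replicate 2. The complement list holds the surfactant genes Sftpa1 and Sftpd, which are also AEC2 markers, so the ranks of these lists are not separate results. Airway markers ranked lower with papain (0.0184; adjusted p = 0.796 with an estimated correlation), and their sum stood at 5413 and 22635 CPM in untreated and 4001 and 23643 CPM in papain libraries. AEC2 markers ranked higher with papain and FK506 (0.00285; adjusted p = 0.718 with an estimated correlation), although Sftpc itself lay lower. Adjusted over the list alone 0 members of these lists passed. The genes with the smallest p were Ndufc1, Aox3, Ube2h and Impdh2-ps beside Retnla for papain, and Tm9sf2, Fzd5, Dusp14, Vps36 and Scarb1 for FK506. For both treatments they were Pim3, Pex14, Rnf11 and Lrpprc beside Retnla, and none had an adjusted p below 0.909.

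In AEC1 libraries, Acta2, the smooth muscle actin gene (chromosome 19, 34240336 to 34255585), and Marcks, an actin-binding protein kinase C substrate gene (chromosome 10, 37133243 to 37138926), rose with papain and FK506 against untreated (limma adjusted p = 0.0333 for both). Acta2 was listed at 0 in both untreated libraries and stood at 1271.9 and 839.8 CPM with papain and FK506, and Marcks at 0 against 723.5 and 613.4 CPM. With papain alone, Acta2 stood at 549.5 and 114.8 CPM and Marcks at 390.7 and 151.7 CPM (adjusted p = 0.142 for both). Nexn, an actin filament protein gene, was listed at 0 in untreated and stood at 428.3 and 513.1 CPM with both agents (adjusted p = 0.0751). Acta2 is also a member of the fibroblast and smooth muscle list, whose sum was higher in the same libraries. A change within type 1 cells cannot be told apart from a change in the share of other cells. The calls of Acta2 and Marcks were lost on leaving out any 1 of the 4 libraries compared (0 genes called in each case). They were also lost with only these groups fitted (adjusted p = 0.349) and with pseudocounts of 0.5 (limma adjusted p = 0.0910) and 1 (0.0574). On recovered reads edgeR gave both an adjusted p of 0.000103 and voom gave Acta2 an adjusted p of 0.346, and over all alternatives that of Acta2 lay between 4.35e-09 and 0.349. Limma called 2 of 8178 genes, with 957 at an unadjusted p under 0.05 against 409 by chance, and edgeR called 29, DESeq2 457 and voom 6. Aqp1, a water channel gene of endothelium and mesothelium, stood at 351.2 and 245.3 CPM against 1948.4 and 1968.9 CPM (log2 difference -2.86, SE 0.39, adjusted p = 0.119).

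With papain alone against untreated AEC1, Spp1 (osteopontin, a secreted matrix protein; chromosome 5, 104435111 to 104441053) stood at 746.5 and 787.3 CPM against 1.1 and 10.4 CPM (log2 difference 6.97, SE 0.94, adjusted p = 0.160). Csf1, the macrophage growth factor gene, stood at 189.5 and 199.9 CPM against 40.4 and 77.1 CPM (1.78, SE 0.66, adjusted p = 0.488). Il33 stood at 0 and 87.1 CPM against 145.9 and 17.3 CPM and Ager at 37.1 and 110.7 CPM against 50.5 and 75.9 CPM. Limma called 0 genes, with 761 at an unadjusted p under 0.05, and edgeR called 15, DESeq2 305 and voom 1. With FK506 added to papain, Ddx21, an RNA helicase gene of ribosome biogenesis, stood at 432.9 and 700.7 CPM against 64.6 and 34.9 CPM (3.33, SE 0.60, adjusted p = 0.651). The MHC class I gene H2-K1 stood at 444.6 and 449.4 CPM against 1114.9 and 1476.2 CPM (-1.67, SE 0.36, adjusted p = 0.651). There limma called 0 genes, with 496 at an unadjusted p under 0.05, and edgeR called 0, DESeq2 84 and voom 1.

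By list in AEC1, the 28 cell cycle genes ranked above the others with papain (camera adjusted p = 0.000235; adjusted p = 0.393 with an estimated correlation) and with both agents against untreated (1.53e-05; adjusted p = 0.289 with an estimated correlation). Birc5 and Nusap1, both of mitosis, rose with both agents adjusted over the list alone. The 12 chemokines ranked higher with papain (0.0105; adjusted p = 0.545 with an estimated correlation) and with both agents (0.000143; adjusted p = 0.324 with an estimated correlation). The sum over all listed chemokines was 753.1 and 698.1 CPM in untreated, 1695.2 and 548.5 CPM with papain, and 1915 and 2298.9 CPM with both agents. Papain replicate 2 thus lay below both untreated libraries in this sum. Adjusted over the list alone, 5 and 6 of the chemokines rose. Among them Ccl2, which attracts monocytes, was listed at 0 in untreated and stood at 121.8 and 73.8 CPM with papain and 325.6 and 206.4 CPM with both agents. Cxcl1, a neutrophil attractant, stood at 14.6 and 0, then 169.4 and 43.1, then 416.6 and 522.5 CPM. The 17 MYC and ribosome biogenesis genes ranked higher with both agents against untreated (1.53e-05; adjusted p = 0.289 with an estimated correlation; 6 rose adjusted over the list alone). They also did so with FK506 added to papain (0.0185; adjusted p = 0.573 with an estimated correlation; only Ddx21 rose). Immediate early genes ranked lower with papain (0.000235; adjusted p = 0.393 with an estimated correlation) and with both agents (0.00306; adjusted p = 0.324 with an estimated correlation).

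Markers of other cells moved in the same AEC1 comparisons. Fibroblast and smooth muscle markers summed to 11366 and 9954 CPM in untreated, 26369 and 16625 CPM with papain and 27218 and 18750 CPM with both agents. They ranked higher with papain (camera adjusted p = 0.00406; adjusted p = 0.393 with an estimated correlation; Acta2, Mgp and Col3a1 rose adjusted over the list alone). They also did with both agents (0.00074; adjusted p = 0.324 with an estimated correlation; 3 rose and Dcn fell). AEC2 markers ranked lower with papain (1.55e-08; adjusted p = 0.393 with an estimated correlation), where the surfactant genes Sftpa1, Sftpb and Sftpc fell adjusted over the list alone. With both agents they ranked lower too (1.29e-06; adjusted p = 0.324 with an estimated correlation), and Lamp3 fell adjusted over the list alone. Mesothelial markers ranked lower with FK506 added to papain (0.000223; adjusted p = 0.573 with an estimated correlation). Adjusted over the list alone 4 of 6 fell, led by the mesothelin gene Msln (410.8 and 588.4 to 65.3 and 172.2 CPM; -2.34, SE 0.60). Against untreated they ranked lower with both agents (5.01e-06; adjusted p = 0.289 with an estimated correlation; 5 fell). Airway markers ranked lower with papain (0.00919; adjusted p = 0.545 with an estimated correlation; Sec14l3 fell), and AEC1 markers with both agents (0.0442; adjusted p = 0.396 with an estimated correlation; 0 passed over the list alone).

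Whether the cell types differed in their responses was tested directly. The effect of FK506 on papain-treated cells differed between ILC2 and basophils for 0 of 7814 genes in limma (409 at an unadjusted p under 0.05, smallest adjusted p 0.136). For Il13 no such difference can be read, since it was listed at 0 in all 7 basophil libraries. The papain effect differed between AEC2 and AEC1 for 0 of 9841 genes (454 at an unadjusted p under 0.05), with Il33 at 3.57 (SE 2.42) and Sftpc at 1.91 (SE 0.64, adjusted p = 0.972). The FK506 effect differed between them for 0 genes (566 at an unadjusted p under 0.05). Without the rounded AEC2 library, edgeR called 19, DESeq2 17 and voom 0 for the FK506 effect. For the papain effect these tools had 1 untreated AEC2 library, so their counts say nothing about a difference in that effect.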

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

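The tests of macrophage markers in basophil libraries, of the near-identical AEC2 pair and of thinned reads were chosen after the results they bear on had been seen.

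The FK506 effect on papain-treated cells differed between ILC2 and basophils for 6 gene lists in camera's interaction test with a preset correlation, and for 0 of them with an estimated correlation. The difference, ILC2 minus basophil, was downward for ILC2 identity genes (adjusted p = 1.22e-06; adjusted p = 0.398 with an estimated correlation), AEC2 markers (0.00022; 0.398), AEC1 markers (0.0314; 0.619) and fibroblast and smooth muscle markers (0.00914; 0.398), and upward for MHC class II genes (0.000121; 0.398) and macrophage, monocyte and dendritic cell markers (0.00331; 0.619). In ILC2 papain with FK506 replicate 3, MHC class II genes summed to 20061 CPM, against 154 and 369 CPM in the other 2 libraries of that group, and in the basophil group with FK506 they summed to 1643, 12538 and 19499 CPM. The cause was not tested.

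The papain effect differed between AEC2 and AEC1 for 3 lists, AEC2 minus AEC1. It was higher for AEC2 markers (adjusted p = 5.35e-13; adjusted p = 0.237 with an estimated correlation; Sftpa1 and Sftpb passed adjusted over the list alone) and for type 2 cytokines and growth factors (0.0319; 0.285), where Il10 and Areg passed over the list alone, and lower for chemokines (0.0429; 0.360). The AEC2 markers summed to 8392 and 12193 CPM in untreated and 3142 and 2068 CPM in papain libraries of AEC1, and to 135344 and 140663 CPM and 166115 and 140392 CPM in those of AEC2. Of these 4 AEC2 libraries 2 are the nearly alike untreated and papain replicates 2. In AEC1, Il10 stood at 19.1 and 74.8 CPM in untreated and was listed at 0 with papain, and in AEC2 it was listed at 0 in all 6 libraries, so its difference holds the AEC1 values alone. Areg stood at 86.4 and 29.9 CPM in untreated AEC1 and was listed at 0 with papain, and in AEC2 it stood at 200 and 70.8 CPM in untreated and 202.9 and 74.8 CPM with papain.

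The near-identity of AEC2 untreated replicate 2 and papain replicate 2 is a pattern that could come from 1 RNA sample or library behind both labels. The lowest chi-square per degree of freedom of the other AEC2 pairs was 19.0 times that of this pair, but this measures the likeness again and does not test its source. A batch shared by libraries numbered 2 is argued against, because papain with FK506 replicate 2 correlated with either library at 0.392 at most. Whether 1 sample lies behind both labels, and which label would then be wrong, stays open, and no biological explanation was tested.

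The basophil libraries listed basophil genes at 0 and genes of macrophages and dendritic cells high, in all 7 libraries. Cells of the macrophage, monocyte and dendritic cell lineages in the sorted material are a candidate explanation that was not tested independently of the pattern. The macrophage list exceeded the basophil list in each library, by a factor of 3.38 at least, which restates the pattern, since basophil genes at 0 lower the basophil sum, and some members are made by other cells: in AEC2 the macrophage list reached 14315 CPM, mostly from Lyz2 and Lyz1. With papain, Ctss stood at 2010.3, 3527.6 and 2826.6 CPM and Csf1r at 1397.3, 1505 and 1517.5 CPM (both listed at 0 in all 6 AEC2 libraries), although a sort for basophils would be meant to remove such cells, and its gate is not given in the labels. Loss of basophil genes in the authors' counting cannot be told apart from the presence of such cells. The 6 basophil genes at 0 in all 7 libraries (Mcpt8, Fcer1a, Ms4a2, Cd200r3, Prss34 and Cyp11a1) had a highest value of 0 CPM in the libraries of the other cell types. That outcome was predicted for such a loss. It does not decide the question, because cell types that do not express these genes would give it too.

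The 1351 genes called between papain and untreated basophils rest on 1 untreated library, which lists 2002 genes above 0. That any lone library gives such a count is argued against, since a treated library alone against the other 5 gave 186 calls at most (papain with FK506 replicate 7) and 0 to 14 for the others. Lower depth is argued against only as far as the depth estimates hold, which are approximate for basophils. Papain with FK506 replicate 7, with an estimated total of 2291576 reads against 2078431 in the untreated library, listed 6401 genes above 0. Thinned to the estimated total of the untreated library, it still had 6367. So little thinning restates the estimates and is not a separate test. Fewer starting cells, a technical failure of that library and the absence of papain remain open, because the design sets them all in the same library.

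Other splits of the samples were counted for comparisons of 3 or more libraries per group. With 3 against 3 there are 10 splits, too few for a share under 0.05. For ILC2 papain against untreated the real value was 0 genes and the highest other split 0 (10 of 10 splits gave at least as many), for papain with FK506 against papain 1 and 1 (2 splits), for papain with FK506 against untreated 0 and 1 (10 splits), and for FK506 in basophils 0 and 1 (10 splits). For the difference between ILC2 and basophils the real value was 0 and the highest of the other splits 11 (100 of 100 splits gave at least as many). Where the real count is 0, every split gives at least as many by construction, so these counts of splits say nothing about chance.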

How the results depend on the processing

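Pseudocounts, robust and array-weight fits, edgeR on recovered reads, every AEC2 count test, the sum over listed genes, fits without the nearly alike AEC2 pair and without basophil papain with FK506 replicates 7 and 8, and leave-one-out fits of the differences between cell types were chosen after the data were seen. The robust and array-weight results were seen before the reported setting was run. Of 298 counts for 29 results under alternatives, 201 equalled the reported count or, where both were above 0, lay within 1.5 times of it, and 97 moved (65 above, 32 below). A count of 0 that stayed at 0 is among the equal ones, and says little where few changed genes could be recovered. Of named genes that passed, 1067 of 1171 values still passed and 104 did not. Nearly all of these values are from basophil papain against the single untreated library, which no alternative could leave out. Outside that comparison, Cxcl2 in ILC2 kept its call in 17 of 21 alternatives. Acta2 and Marcks in AEC1 each kept it in 12 of 20. Of named genes that did not pass, 118 of 2539 values passed and 108 had the opposite sign. The basophil count for papain against untreated (1351) stayed between 973 and 1808, while its part called lower (117) was 65 with no filter, 192 with size factors, 185 with totals, 206 with the listed sum, 207 with array weights, 223 at adjusted p under 0.1 and 68 without papain replicate 5. Except where stated, the cause was not tested.

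For ILC2 papain against untreated (0 genes), size factors gave 2, library totals 3, at least 1 CPM 7, adjusted p under 0.1 3, pseudocount 5 1, the sum over listed genes 2, array weights 9, a robust fit 8 and no batch term 1. For FK506 against papain in ILC2 (1), totals gave 2, at least 1 CPM 3, pseudocount 5 2, the listed sum 2, a robust fit 5 and replicates 1 and 2 only 0. For papain with FK506 against untreated (0), size factors, totals, at least 1 CPM, pseudocount 5 and the listed sum each gave 1, array weights 58 and a robust fit 3. For FK506 in basophils (0), fitting only these groups gave 3, array weights 9 and a robust fit 8.

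In AEC2 (0 in each), FK506 against papain gave 63 with DESeq2 and 5 with voom, both without the rounded library. Both agents against untreated gave 8 with array weights and 6 with a robust fit. The count tests against untreated had 1 untreated AEC2 library, and their counts are not given. In AEC1, papain against untreated (0) gave 8 with array weights, 13 robust, 15 with edgeR, 305 with DESeq2 and 1 with voom. FK506 against papain (0) gave 84 with DESeq2 and 1 with voom. Both agents against untreated (2) gave 0 with only these groups, 0 with pseudocounts 0.5 and 1, 8 with pseudocount 5, 39 with array weights, 38 robust, 29 with edgeR, 457 with DESeq2 and 6 with voom. The ILC2 and basophil difference (0) gave 170 with the basophil file code only, where ILC2 has 1 library per group and its spread is borrowed from the basophil groups, so the 170 describe single ILC2 libraries. The AEC differences (0 each) were also fitted with count tests that left out the rounded AEC2 library. For FK506 edgeR gave 19, DESeq2 17 and voom 0. For papain edgeR gave 14 and DESeq2 3, with untreated replicate 2 as the only untreated AEC2 library. That library is nearly alike with papain replicate 2, so the papain counts say nothing about a difference in the papain effect.

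Leaving out 1 library gave 0 to 5 genes for ILC2 papain against untreated (5 without papain replicate 1, 3 without untreated replicate 1, 1 without papain replicate 2), 0 to 2 for FK506 against papain (0 without replicate 3 of either group, 2 without papain with FK506 replicate 2), 0 to 1 for papain with FK506 against untreated (1 without untreated replicate 1), 1107 to 1250 for basophil papain against untreated, and 0 to 3 for FK506 in basophils (3 without papain replicate 4, 1 without FK506 replicate 9). In AEC2 the range was 0 to 166 for FK506 against papain (166 and 162 without FK506 replicate 1 and 2), 0 to 165 for both agents against untreated (165 and 163), and 0 to 0 for papain. Of these calls 159 were genes at 0 in every library of the replicated groups, whose spread is 0 by construction. In AEC1 it was 0 to 0 throughout, and for the differences 0 to 5 (ILC2 and basophils; 5 without ILC2 papain with FK506 replicate 2, 1 without ILC2 papain replicate 2), 0 to 1 (papain in AEC; 1 without AEC1 papain replicate 1) and 0 to 0. A lone library left in a group was assumed to vary like the others.

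Camera with an estimated correlation called 0 lists in every comparison, against 2, 2 and 1 in ILC2, 11 in basophils with FK506, 3, 1 and 3 in AEC2, 6, 2 and 8 in AEC1, and 6 and 3 in the differences. Fry called 0 in ILC2, in AEC2, for FK506 in basophils, for the ILC2 and basophil difference and for AEC1 except both agents against untreated (6), 13 for papain in basophils, and 2 for the papain difference between AEC2 and AEC1 (1 up, 1 down) and 0 for their FK506 difference. Other scalings moved the median of all genes by 0.17 in ILC2 papain against untreated (from -0.22 to -0.05), 0.14 in ILC2 and 0.13 in AEC2 for both agents against untreated, and 0.12 and 0.11 in AEC1 for FK506 against papain and both agents against untreated.

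With the replicate number as a block, ILC2 gave 2, 1 and 0 genes, AEC2 0 in each comparison, AEC1 0, 0 and 2, and the AEC differences 0. Replicate numbers are those of the titles. The file names of ILC2 papain replicate 2 and papain with FK506 replicate 2 end in 3, so the block and the correlations by number are uncertain for number 2 of ILC2, above all against untreated. The numbers do not pair the samples: same-numbered ILC2 libraries deviated together at r = 0.05 to 0.12 for numbers 1 and 2, and at 0.15 to 0.23 for number 3, which has its own file code. In AEC2 the same-numbered untreated and papain libraries stood at 0.45, the highest value, with the near-identical pair among them, and the other AEC2 and all AEC1 pairs of one number lay between -0.02 and 0.02.

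Not run were DESeq2 and voom for ILC2, basophils and their difference, which have no counts, both tools with all 6 AEC2 libraries, and basophil papain without its only untreated library. Depth limits AEC genes near 1 CPM, which is about 1 read.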

Other observations

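Beyond the lists above, single ILC2 libraries differed in the transcripts of other lung cells. Scgb1a1, the club cell secretoglobin gene, stood at 24968 CPM in untreated ILC2 replicate 3, was listed at 0 in the other 2 untreated libraries and in all 3 papain libraries, and stood at 0, 68 and 69 CPM with papain and FK506. The MHC class II gene H2-Aa stood at 6777 CPM in ILC2 papain with FK506 replicate 3, and at 0 and 51 CPM in the other 2 libraries of that group. In the same library Thy1 and Klrg1, surface proteins of ILC2, were listed at 0, against 798 and 476 CPM and 550 and 123 CPM in the others.

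In AEC2 the surfactant protein D gene Sftpd stood at 13886 CPM in papain replicate 1 and at 11699.9 and 13495.1 CPM with papain and FK506, against 5714 and 5383.3 CPM in untreated libraries and 5637.5 CPM in papain replicate 2, the library nearly alike with untreated replicate 2. Scgb1a1 in AEC2 stood at 1920 and 18499 CPM in untreated, 2362.4 and 19332.8 CPM with papain and 9424.6 and 9923.9 CPM with papain and FK506. In AEC1, Pdpn, which encodes podoplanin of type 1 cells and of stromal and mesothelial cells, stood at 98.8 and 125.4 CPM in untreated, 368.5 and 310.6 CPM with papain and 229.9 and 432.9 CPM with both agents.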
